A study of Mus musculus with 12 samples.

How the data were processed

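RNA of mouse embryonic stem cells was measured on 12 Affymetrix MG_U74Av2 arrays, 3 from cells kept in phosphate-buffered saline (PBS), 4 from cells given the low dose of hydrogen peroxide and 5 from cells given the high dose. Groups and replicate numbers were taken from the sample titles. The deposited table holds 1 value per probe set and array, an intensity on a linear scale. Per the submitters' processing notes these values are MAS5 signals, which weigh each perfect-match probe against its mismatch partner. The MAS5 version, the scaling target and the detection calls are not given in the sources used here. In the deposited values every array had the same mean after trimming 2% at each end, to within 0.0195% between the highest and the lowest array, so the deposited scaling was kept, a choice that a planned tolerance of 10% allowed. Arrays have no read depth; the number of arrays per group limits the precision.

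The intensities were put on a log2 scale after adding 10.1 signal units, the 20th percentile of all values. Fold changes are therefore on the log2(signal + offset) scale, which understates the changes of dim probe sets. The 66 Affymetrix control probe sets were left out of the tests and used as quality measures. Of the 12488 probe sets on the array, those with a mean log2 value over the 12 arrays above the 30th percentile of the others were tested, 8695 in all. Gene names came from a platform annotation table, updated by Entrez number through RefSeq gene records of assembly GRCm38.p6, which was used for names only. By that annotation 10855 probe sets had 1 gene symbol and 396 had several, while 1193 outside the controls were not listed. Of those with 1 symbol, 10839 were matched by Entrez number. No gene was named from a probe set with several symbols. The array files carry no genome build, so no coordinates are given.

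A linear model with a mean per group was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3, with moderated variances that follow the mean level (eBayes with a trend), so the 3 groups shared 1 estimate of the spread. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over the 8695 probe sets, with 0.05 as the threshold. Standard errors (SE) are the moderated ones of the model. For statements about genes, the probe set with the highest mean log2 value stood for each of 6414 genes; 1167 of them had more than 1 tested probe set. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 30 lists within a comparison, and again with an estimated correlation and with limma's fry. Array quality measures, 22 in number, were compared by exact two-sided permutation tests. The smallest p these allow is 0.0179 for 5 against 3 arrays, 0.0286 for 4 against 3 and 0.00794 for 5 against 4.

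The groups, tests, gene lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule takes, per comparison, the 12 largest rises and the 12 largest falls among genes past the threshold whose arrays do not overlap between the groups. It adds up to 4 members per list, those with the largest change past the threshold, or the 2 with the largest change where none passed. It always names Cdkn1a, Mdm2, Hmox1, Fos, Jun, Egr1, Atf3, Ddit3, Hspa1a, Hspa1b, Pou5f1, Sox2, Nanog, Gapdh and Actb where measured. The probe set of Jun was below the filter, and those of Gapdh outside the control probe sets carry several symbols. Further genes, chosen after their values were seen, are named where a list's members are counted out and in the closing section.

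The lists covered p53 targets, Nrf2 targets, antioxidant enzymes, immediate-early genes, the heat shock response, the unfolded protein and integrated stress response, double-strand break repair, base excision and single-strand break repair, mismatch and nucleotide excision repair, pluripotency, primitive endoderm markers, mesoderm and ectoderm markers, fibroblast (feeder) markers, S-phase genes, G2/M genes, apoptosis regulators, NF-kB targets, the metal response, cholesterol synthesis, glycolysis, the hypoxia response, labile chromatin and transcription regulators, cytosolic ribosomal proteins, the mitochondrial respiratory chain, mitochondrial ribosomal proteins, the proteasome, zinc-finger (Zfp) genes, histone genes, translation initiation and elongation factors, and splicing factors with heterogeneous nuclear ribonucleoproteins.

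The steps were tested on simulated data with 200 of the 8695 probe sets changed. For high dose against control 67% of changes of log2 1 and 99% of log2 2 were recovered with 9 false calls, for low dose against control 62% and 95% with 7, and for high against low dose 82% and 98% with 7. The alternatives tried were quantile normalization, scaling to a common median, a floor in place of the offset, 4 times the offset, no filter and a filter at the 50th percentile, no variance trend, array quality weights, only the groups compared, the replicate number as an additive term, a 2-fold minimum, other probe sets of a gene and the omission of each array in turn. Leaving out the probe sets with a mean signal above 2000 (420 of those tested), and leaving out control replicate 1 and high-dose replicate 2 together, were chosen after seeing the data. All 12 arrays were used.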

Results

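Gene expression was measured in 12 samples of mouse embryonic stem cells on MG_U74Av2 arrays, which read each transcript with 1 or more sets of short oligonucleotides (probe sets). The cells were clone C2, a derivative of the E14tg2a embryonic stem cell line carrying targeted recognition sites for I-SceI. I-SceI is an endonuclease used to make DNA breaks at such sites. Control cells were held in PBS (n = 3). Treated cells received hydrogen peroxide, a membrane-permeable oxidant, in PBS at 100 µM for 15 min (low dose, n = 4) or at 5 mM for 30 min (high dose, n = 5), and RNA was taken after 1 h of recovery in maintenance medium. Concentration and exposure time differ together between the doses, so each comparison is between treatments as given. The time the controls spent in PBS, and whether they had a recovery in maintenance medium, are not given in the sources used here. In comparisons with the controls, an effect of the return to medium therefore cannot be told apart from one of peroxide. The labels do not say whether replicates are separate cultures, so p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision of every value.

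Across probe sets, which are not independent replicates, arrays of the same group correlated at r = 0.958 to 0.978 (19 pairs) and arrays of different groups at r = 0.921 to 0.957 (47 pairs). The groups differed at the bright end of the scale. The brightest probe set read 8211 ± 891 (SD, n = 3) on the control arrays, 19629 ± 4699 (n = 4) at the low dose and 27223 ± 6768 (n = 5) at the high dose. Exact two-sided permutation tests gave p = 0.0286 for the low dose and p = 0.0179 for the high dose, the smallest values possible (0.105 and 0.0561 after adjustment over 22 measures). A signal ceiling on the control arrays stays open as a source. Folds of bright genes against the controls, given below, are therefore not established as changes in RNA. The 3′/5′ signal ratio of the Actb control probe sets, a measure of RNA integrity, was 1.26 ± 0.635 in the controls, 1.32 ± 0.166 at the low dose and 1.23 ± 0.162 at the high dose. The wide control spread came from control replicate 1, at 1.99 against 0.871 and 0.921 on the other control arrays.

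**Figure D1:**
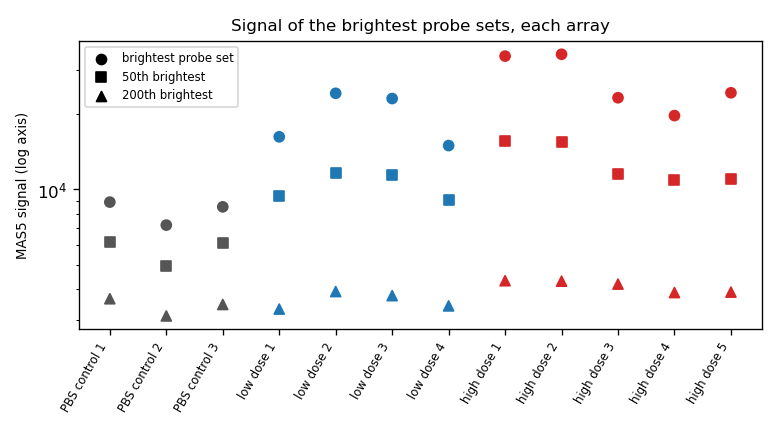
MAS5 signal (log axis) of the brightest, the 50th and the 200th brightest probe set on each of the 12 arrays; each marker is 1 array. The brightest probe set read 8904 at most on a control array and at least 14976 on a treated array.

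The first question was which transcripts differed from the controls after the high dose. Markers of primitive endoderm, the extraembryonic lineage that arises beside the pluripotent cells of the blastocyst, were far lower. Dab2, an endocytic adaptor of this lineage, read 577 ± 67.4 (SD, n = 3) in the controls and 28.6 ± 13.5 (n = 5) at the high dose, a log2 change of -4.00 ± 0.24 (SE) or 16.0-fold (adjusted p = 2.4e-08). The basement membrane collagen genes Col4a1 and Col4a2 fell 11.8-fold and 9.53-fold, the endocytic receptor gene Cubn 11.3-fold, the growth factor receptor gene Pdgfra 7.58-fold, and the endoderm transcription factor genes Sox17 and Gata6 6.40-fold and 5.87-fold. In the same comparison the stress gene Hspa1a, which encodes an inducible chaperone, rose 8.30-fold and the immediate-early gene Fos 5.71-fold.

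Of the 19 measured primitive endoderm markers, 13 fell, 1 rose and 5 did not pass (14 fell and 1 rose when adjusted over the list alone). The median log2 change was -2.21 (camera adjusted p = 1.5e-15, and adjusted p = 0.0176 with an estimated correlation). The member that rose was Apoe, a lipid-carrying apolipoprotein made by many cell types, at a log2 change of 1.09. At its control signal (5731) a ceiling on the control arrays stays open, so this is not established as a change in RNA. The values that did not pass were -0.90 for Foxa2, -0.17 for Ttr, -0.11 for Gata4, 0.01 for the laminin gene Lamc1 and 0.07 for Afp. Among dimmer probe sets of these genes, 1 of Sox17 (-2.95) and 1 of Dab2 (-1.25) fell as well. Others did not pass, with values of -0.62 for Dab2, 0.01 and -0.98 for Gata6, 0.52 for Pdgfra and 0.34 for Cubn. Among the 12 largest falls were also Hs3st1, a heparan sulfate sulfotransferase gene, the forkhead factor gene Foxq1, the cathepsin gene Ctsh (7.02-fold, a log2 change of -2.81 that was -2.21 without control replicate 1), the proteoglycan gene Srgn (5.86-fold) and the matrix protein gene Sparc (5.62-fold). Sparc read 2034 on control replicate 1 against 713.5 and 689.5 on the other control arrays. The means of Hs3st1 (103 to 2.04) and Foxq1 (90.5 to 8.68) ended below the offset, so the size of their falls depends on it, at log2 -3.07 and -2.48, or -5.13 and -3.68 with a floor instead. The epithelial keratin genes Krt18 and Krt8 fell 3.26-fold and 2.99-fold. Both were on the list of mesoderm and ectoderm markers, of whose 14 measured members 2 fell and 12 did not pass (adjusted p = 0.755). None of 16 fibroblast (feeder) markers passed in limma (3 had an unadjusted p under 0.05, and the list's adjusted p was 0.991 by camera and 0.99 by fry); the largest values were -0.99 for Timp3 and -0.78 for Tagln (-1.28 and an adjusted p of 0.0487 without control replicate 2).

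**Figure D2:**
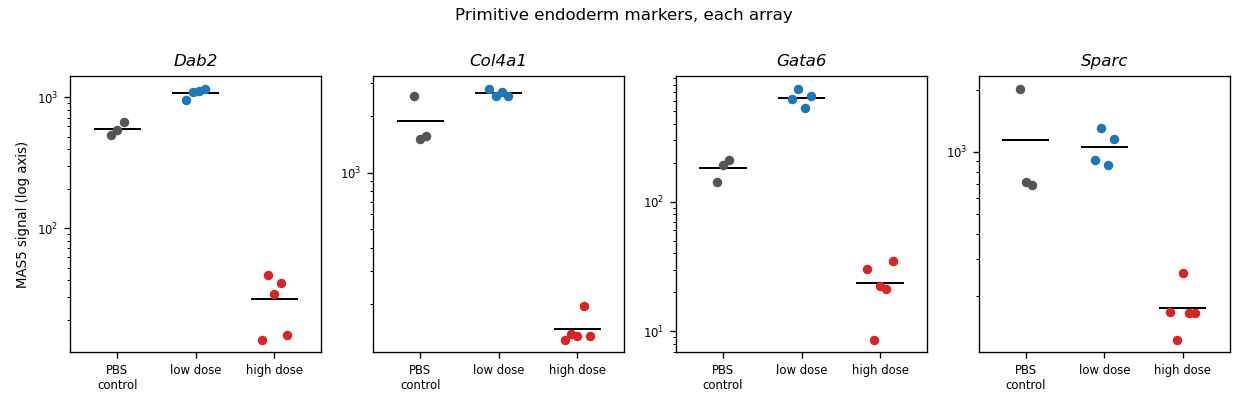
MAS5 signal (log axis) of the primitive endoderm markers Dab2, Col4a1, Gata6 and Sparc on each array; dots are arrays and horizontal lines are group means. Mean Dab2 signal was 577 in the controls, 1088 at the low dose and 28.6 at the high dose.

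Cytosolic ribosomal protein genes were higher after the high dose, together with the other bright probe sets. Of the 33 genes on this list, 18 rose, 2 fell and 13 did not pass (21 rose and 2 fell when adjusted over the list alone), with a median log2 change of 0.80 (camera adjusted p = 1.3e-12). The call was lost with an estimated correlation (adjusted p = 0.14 with an estimated correlation) and after quantile normalization (adjusted p = 0.196). Without probe sets of mean signal above 2000, a setting chosen after seeing the data, the median was -0.05. Rpl41 read 157 ± 111 (SD, n = 3) in the controls and 27220 ± 6768 (n = 5) at the high dose, a log2 change of 7.60 ± 0.37 (SE) that was 6.94 without control replicate 3. Rpl8 (4589 in the controls) and Rpl19 (4217) read 4.27-fold and 4.07-fold higher, with a signal ceiling on the control arrays open as a source. A dimmer probe set of Rpl19 gave -0.42 and did not pass. The members that fell were Rpl39l, a paralog of Rpl39 expressed mainly in testis, at -1.43, and Rps6kc1, at -0.84, which belongs to a kinase family and is not a part of the ribosome. The kinase gene Rps6kb2, also on this list by its name, had a value of -0.51. Other bright genes read higher as well: the elongation factor gene Eef1a1 5.68-fold, the glycolytic genes Pkm 3.20-fold and Aldoa 2.28-fold, and the chromatin corepressor gene Trim28 3.15-fold. With a signal ceiling on the control arrays open as a source, the folds of these bright genes are not established as changes in RNA. Dimmer probe sets of Pkm and Aldoa gave -0.03 and 0.24, and neither passed. Ldha, the lactate dehydrogenase A gene, rose 1.93-fold with the deposited scaling and had a log2 value of -0.25 after quantile normalization.

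In the metal response, 4 of 6 genes rose and 2 did not pass (4 rose when adjusted over the list alone), with a median of 0.81 (camera adjusted p = 2.3e-04, and adjusted p = 0.0282 with an estimated correlation). The median was 0.49 without probe sets of mean signal above 2000 (adjusted p = 0.0479). Mt2 and Mt1, which encode metal-binding metallothioneins and are read by probe sets above that signal, had values 4.39-fold and 2.08-fold higher, while the zinc exporter gene Slc30a1 rose 1.94-fold and the heme oxygenase gene Hmox1 1.57-fold. Histone genes had a median of 0.51 (camera adjusted p = 0.00216, and adjusted p = 0.14 with an estimated correlation). Of 14, 3 rose and 11 did not pass (3 rose when adjusted over the list alone), with the linker histone gene H1f1 2.75-fold higher. Of 44 splicing factors and heterogeneous nuclear ribonucleoproteins, 7 rose (8 when adjusted over the list alone) and 37 did not pass, with a median of 0.16 (camera adjusted p = 0.00591, and adjusted p = 0.378 with an estimated correlation). Snrpb (3554 in the controls), a core component of spliceosomal particles, read 2.21-fold higher, with a signal ceiling on the control arrays open as a source. The splicing factor gene Srsf6 rose 1.64-fold. Without control replicate 2 the adjusted p was 0.0789 for this list and 0.0595 for Srsf6, and for the list it was 0.0504 after quantile normalization and 0.0864 without probe sets of mean signal above 2000.

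None of the 20 measured p53 targets passed after the high dose in limma. At an unadjusted p under 0.05 there were 7, adjusted over the list alone 1 was higher and 4 lower, and the list's adjusted p was 0.377 by camera and 0.0675 by fry. Mdm2, the ubiquitin ligase gene that restrains p53, had a log2 value of -0.40 ± 0.21 (SE, adjusted p = 0.247) and the cell cycle inhibitor gene Cdkn1a -0.05 ± 0.19 (adjusted p = 0.901). Of 36 immediate-early genes 7 rose, 3 fell and 26 did not pass (8 rose and 7 fell when adjusted over the list alone), with a median of 0.02 (adjusted p = 0.755). Egr1 rose 1.91-fold, the orphan receptor gene Nr4a1 had a log2 change of -0.73, and Atf3 had a value of 0.31 (adjusted p = 0.43; without control replicate 1 it was 0.68, adjusted p = 0.033). In the heat shock response 5 of 19 genes rose, 2 fell and 12 did not pass (5 rose and 2 fell when adjusted over the list alone; adjusted p = 0.0719). Hspa1b rose 2.69-fold, and Serpinh1, a chaperone of collagen, fell 4.65-fold. Hsp90aa1 (2994 in the controls) read 4.19-fold higher, with a signal ceiling on the control arrays open as a source. The unfolded protein and integrated stress response had 7 of 29 genes higher and 1 lower (7 and 2 when adjusted over the list alone; adjusted p = 0.0719), with the serine synthesis gene Psat1 1.77-fold higher and the value of Ddit3, a transcription factor gene of this response, at 0.05 (adjusted p = 0.954).

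The pluripotency list held 40 measured genes, of which 7 rose, 4 fell and 29 did not pass (11 rose and 6 fell when adjusted over the list alone), with a median of 0.06 (adjusted p = 0.438). Lefty1, an inhibitor of Nodal signalling, rose 3.79-fold, and Socs3, a feedback inhibitor of LIF signalling, fell 2.19-fold (another of its probe sets gave -0.32 and did not pass). Nanog rose 1.43-fold, but its adjusted p was 0.0618 without control replicate 2, 0.0603 without control replicate 3, 0.172 after quantile normalization and 0.106 after median scaling, and a dimmer probe set gave -0.59. The values of Pou5f1 and Sox2 were 0.47 (adjusted p = 0.0821; 0.0446 without low-dose replicate 2) and -0.23 (adjusted p = 0.349; -0.46 and 0.0117 after quantile normalization). Both probe sets of Actb outside the control probe sets were dim and variable, at 228 ± 92.1 (SD, n = 3) in the controls and 250 ± 278 (n = 5) at the high dose for one and at 167 ± 126 and 145 ± 184 for the other, and neither passed. Napsa, an aspartic protease gene, and Trh, a hormone precursor gene, rose 4.45-fold and 3.71-fold. Skil, a repressor of TGF-beta signalling, rose from 9.24, below the offset, to 96.6, a log2 change of 2.41, or 3.33 with a floor instead.

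The remaining lists did not pass by camera after the high dose. By fry, antioxidant enzymes (adjusted p = 0.0334) and S-phase genes (0.0275) passed. Of the lists above that camera did not call, fry called pluripotency (0.00722), the unfolded protein and integrated stress response (0.008) and the heat shock response (0.0275). Of 23 Nrf2 targets 2 rose and 2 fell (adjusted p = 0.961), with the glutathione transferase gene Gstp1 2.52-fold lower, and of 20 antioxidant enzymes 1 rose and 2 fell (adjusted p = 0.422), with the glutathione peroxidase gene Gpx3 2.83-fold lower. Among DNA repair lists, 1 of 25 double-strand break repair genes fell (Xrcc6, log2 change -0.58; adjusted p = 0.991) and 1 of 17 mismatch and nucleotide excision repair genes rose and 2 fell (adjusted p = 0.961). None of 18 base excision and single-strand break repair genes passed in limma (1 at an unadjusted p under 0.05; list adjusted p = 0.991 by camera and 0.759 by fry), with values of 0.39 for Parp2 and -0.51 for Xrcc1. The adjusted p of Xrcc1 was 0.0697, and it was 0.0238 without control replicate 1, 0.0474 without low-dose replicate 3 and 0.0295 after median scaling. Of 29 S-phase genes 1 rose and 4 fell (adjusted p = 0.422), of 35 G2/M genes 3 rose and 3 fell (adjusted p = 0.985), and of 29 apoptosis regulators 1 rose and 1 fell (adjusted p = 0.749), the latter being Apaf1, an activator of caspases, at 2.08-fold. NF-kB targets (13 genes, 1 higher and 1 lower) gave an adjusted p of 0.991, cholesterol synthesis (18 genes, 1 lower) 0.379, glycolysis (19 genes, 4 higher and 3 lower) 0.598 and the hypoxia response (16 genes, 2 higher and 4 lower) 0.347. Labile chromatin and transcription regulators (42 genes, 3 higher and 3 lower) gave 0.961, the mitochondrial respiratory chain (65 genes, 6 higher and 3 lower) 0.961, mitochondrial ribosomal proteins (58 genes, 4 higher and 6 lower) 0.445 and the proteasome (35 genes, 4 higher and 2 lower) 0.347. Zinc-finger genes (75 genes, 4 higher and 4 lower) gave 0.504 and translation initiation and elongation factors (46 genes, 5 higher and 5 lower) 0.522.

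In all, 1018 of 8695 probe sets differed between the high dose and the controls, 494 higher and 524 lower, and 280 of them by at least 2-fold. By gene, 344 of 6414 were higher and 439 lower. The count of 1018 became 490 without control replicate 2 and 599 without control replicate 3, and with each array scaled to a common median 309 were higher and 618 lower. Of the 30 lists, 5 passed, 4 up and 1 down, a number that was 8 without control replicate 1 and 3 after quantile normalization.

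The second question was which transcripts differed after the low dose. Targets of the stress-activated transcription factor p53 were higher. Plk2, a polo-like kinase gene, read 863 ± 236 (SD, n = 3) in the controls and 3227 ± 407 (n = 4) at the low dose, a log2 change of 1.92 ± 0.17 (SE) or 3.79-fold (adjusted p = 3.6e-06). Mdm2 rose 3.30-fold, the cyclin gene Ccng1 2.96-fold and Cdkn1a 1.97-fold. Of 20 measured p53 targets 8 rose, 2 fell and 10 did not pass (9 rose and 2 fell when adjusted over the list alone), with a median of 0.41 (camera adjusted p = 0.00524, and adjusted p = 0.111 with an estimated correlation). The members that fell were the growth arrest gene Gadd45a (-0.70) and the DNA damage recognition gene Xpc (-0.66), and the call of Xpc was lost without control replicate 1 (adjusted p = 0.0668), control replicate 2 (0.0661), low-dose replicate 2 (0.0538) or low-dose replicate 3 (0.0598).

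Immediate-early genes, transcribed within minutes of a stimulus, were higher as well. Of 36 measured, 17 rose, 3 fell and 16 did not pass (19 rose and 4 fell when adjusted over the list alone), with a median of 0.48 (camera adjusted p = 2.0e-05, and adjusted p = 0.111 with an estimated correlation). Fos rose 8.80-fold, from 80.8 ± 37.9 (SD, n = 3) to 743 ± 110 (n = 4), Atf3 3.69-fold, the antiproliferative gene Btg1 3.50-fold and Egr1 2.16-fold. Myc, the growth-promoting transcription factor gene on this list, fell 2.57-fold. Metallothionein genes Mt2 and Mt1 had values 4.62-fold and 4.10-fold higher, and Slc30a1 rose 2.61-fold. In the metal response 3 of 6 genes rose and 3 did not pass (3 rose when adjusted over the list alone), with a median of 0.84 (camera adjusted p = 0.0109, and adjusted p = 0.111 with an estimated correlation). Without probe sets of mean signal above 2000, which include both metallothionein genes, the median was 0.18 (adjusted p = 0.428). Hmox1 had a value of 0.08 (adjusted p = 0.702).

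**Figure D3:**
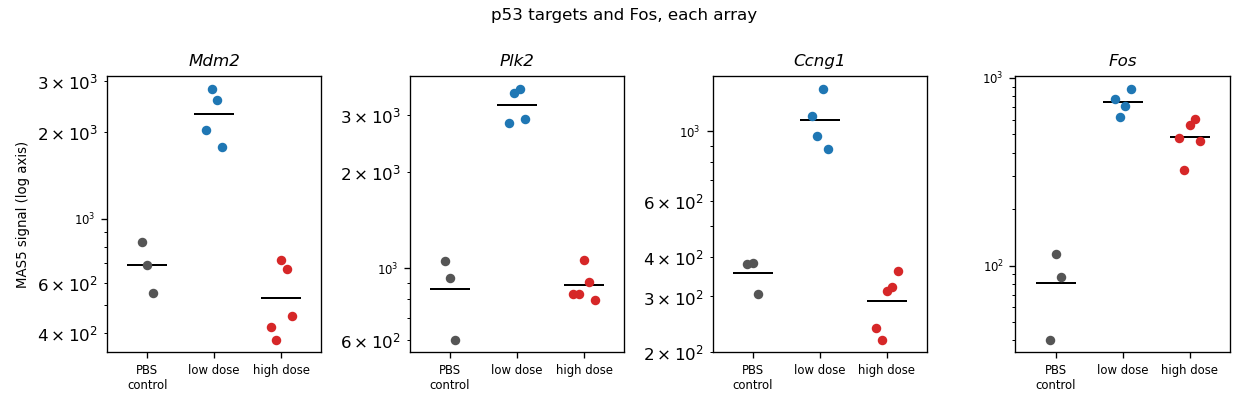
MAS5 signal (log axis) of the p53 targets Mdm2, Plk2 and Ccng1 and of the immediate-early gene Fos on each array; dots are arrays and horizontal lines are group means. Mean Mdm2 signal was 691 in the controls, 2308 at the low dose and 530 at the high dose.

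In the heat shock response 5 of 19 genes rose, 1 fell and 13 did not pass (10 rose and 1 fell when adjusted over the list alone), with a median of 0.38 (camera adjusted p = 0.00846, and adjusted p = 0.21 with an estimated correlation; 0.0707 without probe sets of mean signal above 2000). The small heat shock protein gene Hspb8 rose 2.50-fold. Hsp90aa1 (2994 in the controls) and the mitochondrial chaperonin gene Hspe1 (3299) read 2.92-fold and 1.77-fold higher. For both, a signal ceiling on the control arrays stays open as a source. Hspa1a and Hspa1b had values of 0.68 (adjusted p = 0.063) and 0.62 (adjusted p = 0.0589); that of Hspa1a was 0.0268 without high-dose replicate 2 and 0.0456 without high-dose replicate 3, and that of Hspa1b 0.046 without high-dose replicate 1, 0.0461 without replicate 2 and 0.0251 without replicate 3. Hspa4, the member that fell (-0.73), has another probe set that passed at -0.43 and 3 that did not, at 0.05, 0.40 and -0.06. Cytosolic ribosomal protein genes were higher, again with other bright probe sets: 19 of 33 rose, 2 fell and 12 did not pass (23 rose and 3 fell when adjusted over the list alone), with a median of 0.77 (camera adjusted p = 4.3e-08, and adjusted p = 0.213 with an estimated correlation). Rpl41 had a log2 change of 7.13 ± 0.38 (SE), which was 6.46 without control replicate 3. Rpl8 (4589 in the controls) and Rps18 (4925) read 3.06-fold and 3.03-fold higher, with a signal ceiling on the control arrays open as a source. The members that fell were Rpl39l (-1.33) and the kinase gene Rps6kb2 (-1.15). Without probe sets of mean signal above 2000 the median was 0.45 (adjusted p = 0.636).

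Mitochondrial ribosomal protein genes and proteasome genes were lower after the low dose. Of 58 mitochondrial ribosomal protein genes 22 fell and 36 did not pass (23 fell when adjusted over the list alone), with a median of -0.29 (camera adjusted p = 2.7e-07, and adjusted p = 0.111 with an estimated correlation). Mrpl34 fell 2.04-fold, Mrpl58 1.95-fold and Mrpl23 1.93-fold. Of 35 proteasome genes 9 fell and 26 did not pass (9 fell when adjusted over the list alone), with a median of -0.11 (camera adjusted p = 0.00561, and adjusted p = 0.297 with an estimated correlation; without control replicate 1, median -0.05 and adjusted p = 0.0782; without control replicate 2, median -0.19). The catalytic subunit genes Psmb10 and Psmb6 fell 2.23-fold and 2.17-fold, and the regulatory subunit gene Psmd8 fell 2.13-fold.

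Single genes with large falls after the low dose included S100a6, a calcium-binding protein gene, which read 1135 ± 670 (SD, n = 3) in the controls and 58.8 ± 16.1 (n = 4) at the low dose, a log2 change of -3.92 ± 0.28 (SE; adjusted p = 6.9e-07). The cyclin-dependent kinase inhibitor gene Cdkn1c fell 8.38-fold, the growth factor gene Fgf17 5.26-fold, the metalloprotease gene Adam19 4.76-fold and the tight junction gene Cldn6 3.73-fold. The other large falls were in Rarg, Fxyd3, Tmsb4x, Cds2, Gbx2, Tcea3 and Hmces, with log2 changes between -2.07 and -1.87. Among the large rises were Fst, an activin antagonist gene (5.45-fold), Eef1a1 (4.51-fold), Id4, an inhibitor of helix-loop-helix factors (4.10-fold), the immunoglobulin segment Ighv3-6 (3.96-fold) and Jade1, a histone acetylation scaffold gene (3.95-fold). For Eef1a1 a signal ceiling on the control arrays stays open as a source. Uhmk1, a kinase gene, rose 5.15-fold with a wide spread, and its adjusted p was 0.0562 without control replicate 2 and 0.0517 without low-dose replicate 2.

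Of the 19 primitive endoderm markers 6 rose and 13 did not pass after the low dose (6 rose when adjusted over the list alone), and the list missed the threshold (median 0.28, camera adjusted p = 0.0503). The transcription factor genes Foxa2 and Gata6 rose 6.14-fold and 3.39-fold, and Dab2 1.87-fold (adjusted p = 0.0551 with a floor in place of the offset; its other probe sets passed at 1.07 and 1.00). Other probe sets of Gata6 gave 0.63 and -0.0027, and neither passed. The pluripotency list had 13 of 40 genes higher and 7 lower (14 and 9 when adjusted over the list alone; adjusted p = 0.23). Its members Tbx3 and Klf4, transcription factors of naive pluripotency, rose 3.22-fold and 2.81-fold and Nanog 1.64-fold (0.58 on the log2 scale in a dimmer probe set, not passing), while the germ cell and oocyte factor gene Dppa3 fell 2.84-fold and Id1 2.73-fold. Sox2 had a log2 change of 0.61, not past the threshold without control replicate 2 (adjusted p = 0.0545) or after median scaling (0.125), and Pou5f1 a value of 0.10 (adjusted p = 0.726). Ddit3 had a value of -0.28 (adjusted p = 0.708) and Actb of 0.62 (adjusted p = 0.518; -0.14 in its other probe set, not passing).

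In all, 2087 of 8695 probe sets differed between the low dose and the controls, 1110 higher and 977 lower, and 536 of them by at least 2-fold. By gene, 761 of 6414 were higher and 817 lower. Scaling each array to a common median shifted the median log2 change of all tested probe sets by -0.17 in this comparison and by 0.10 in that of high with low dose, and gave 572 higher and 1498 lower. Of the 30 lists 7 passed, 5 up and 2 down. With an estimated correlation camera called 0, with 6 at an unadjusted p under 0.05, and fry called 15.

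**Figure D4:**
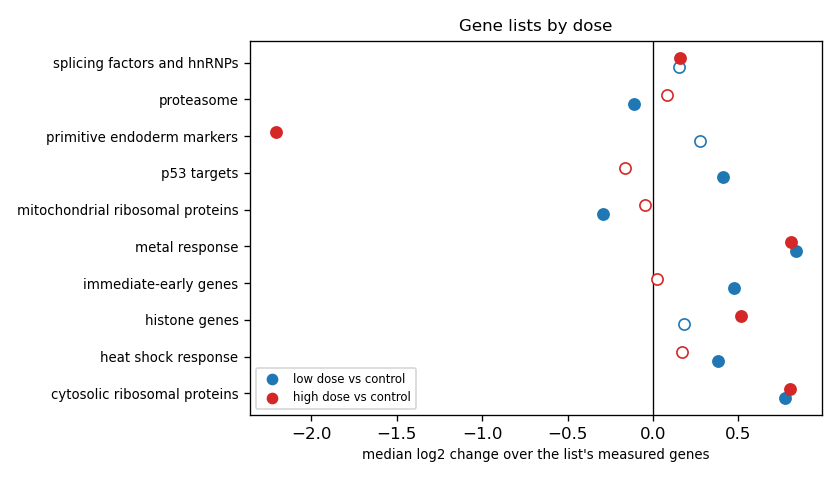
Median log2 change against the controls, over each list's measured genes, for the 10 lists that passed the camera test at either dose; blue is the low dose, red the high dose, filled markers passed and open markers did not. Primitive endoderm markers stood at 0.28 at the low dose and -2.21 at the high dose.

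The third question was how the treatments differed from each other. Primitive endoderm markers were lower after the high dose than after the low dose: Dab2 by 29.9-fold, from 1088 ± 91.6 (SD, n = 4) to 28.6 ± 13.5 (n = 5), a log2 difference of -4.90 ± 0.22 (SE, adjusted p = 3.7e-10). Gata6 was 19.9-fold, Col4a1 17.0-fold and Pdgfra 16.4-fold lower. Foxa2 went from 234 to 11.25, near the offset, a log2 difference of -3.52, or -4.39 with a floor instead. Of 19 markers 14 were lower, 1 (Apoe, 0.83) was higher and 4 did not pass (14 lower and 1 higher when adjusted over the list alone), with a median of -2.48 (camera adjusted p = 3.3e-12, and adjusted p = 0.0398 with an estimated correlation). Dimmer probe sets of Dab2 (-2.32 and -1.62), Sox17 (-3.12) and Gata6 (-0.98) were lower too, while others did not pass, at -0.62 for Gata6, -0.32 for Pdgfra and -0.16 for Cubn. Amot, a regulator of Hippo signalling, Srgn, Serpinh1 and Gpx3 were 10.9-fold, 8.09-fold, 6.06-fold and 4.87-fold lower. The offset lowers these folds for dim genes: with a floor the log2 difference was -5.40 instead of -4.90 for Dab2, -4.89 instead of -4.31 for Gata6, -4.58 instead of -4.04 for Pdgfra and -3.88 instead of -3.02 for Srgn. Foxq1 and Hs3st1, below the offset at the high dose, had log2 differences of -4.27 and -3.38, or -5.59 and -5.48 with a floor instead.

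Of 20 p53 targets 11 were lower after the high dose than after the low dose, 1 (Xpc, 0.66) was higher and 8 did not pass (12 lower and 1 higher when adjusted over the list alone), with a median of -0.46 (camera adjusted p = 3.1e-04, and adjusted p = 0.088 with an estimated correlation). Mdm2 was 4.36-fold, Ccng1 3.64-fold, Plk2 3.61-fold and Cdkn1a 2.03-fold lower. Of 36 immediate-early genes 15 were lower, 2 were higher and 19 did not pass (17 lower and 2 higher when adjusted over the list alone), with a median of -0.49 (camera adjusted p = 2.3e-04, and adjusted p = 0.145 with an estimated correlation). The matricellular gene Ccn2 was 4.47-fold, Btg1 3.49-fold, Klf4 3.27-fold and Atf3 2.98-fold lower, and the higher members were Myc (0.95) and Gadd45g (0.84). Fos had a value of -0.62 (adjusted p = 0.0525; 0.0107 without control replicate 1, 0.0323 without control replicate 2, 0.0407 without high-dose replicate 4 and 0.0478 after quantile normalization) and Egr1 of -0.18 (adjusted p = 0.456).

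Genes higher after the high dose than after the low dose included Cdkn1c, which read 42.8 ± 11.6 (SD, n = 4) at the low and 655 ± 77.7 (n = 5) at the high dose, 12.8-fold higher (log2 3.68 ± 0.17 SE, adjusted p = 4.4e-10). S100a6 was 9.90-fold, Fgf17 8.22-fold and Hspa1a 5.18-fold higher, followed by the calmodulin-like gene Calml4 (5.14-fold), the fatty acid transporter gene Slc27a1 (5.01-fold), Plac8 (4.94-fold), the neuronal genes Gap43 (4.24-fold) and Ina (4.22-fold), and the cytokine gene Ltb (4.11-fold). Of 58 mitochondrial ribosomal protein genes 21 were higher, 2 were lower and 35 did not pass (22 higher and 3 lower when adjusted over the list alone), with a median of 0.24 (camera adjusted p = 6.3e-05, and adjusted p = 0.137 with an estimated correlation), and Mrpl23 was 2.67-fold higher. Of 35 proteasome genes 15 were higher and 20 did not pass (15 higher when adjusted over the list alone), with a median of 0.26 (camera adjusted p = 6.3e-05, and adjusted p = 0.274 with an estimated correlation), and Psmb10 and Psmb6 were 1.99-fold and 1.98-fold higher. Without probe sets of mean signal above 2000 the adjusted p of the proteasome list was 0.0644. Cytosolic ribosomal protein genes had a median of 0.14 (2 higher and 2 lower of 33, adjusted p = 0.613). Hmox1 was 1.49-fold, Hspa1b 1.76-fold and Lefty1 3.86-fold higher, Sox2 was 1.79-fold lower, and Nanog and Pou5f1 had values of -0.19 (adjusted p = 0.215) and 0.37 (adjusted p = 0.0858). After quantile normalization the adjusted p of Nanog was 0.0133, and its dimmer probe set gave -1.17 (adjusted p = 0.00176). After median scaling the adjusted p of Pou5f1 was 0.0261.

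In all, 2385 of 8695 probe sets differed between the doses, 1113 higher and 1272 lower after the high dose, and 539 of them by at least 2-fold. By gene, 886 of 6414 were higher and 972 lower. With each array scaled to a common median 1404 were higher and 872 lower. Of the 30 lists 5 passed, 2 up and 3 down, and 1 passed with an estimated correlation. Over the 3 comparisons the median, the mean and the camera direction of a list had the same sign in each of the 17 list results that passed. Among lists that did not pass they differed in sign after the high dose for double-strand break repair, mesoderm and ectoderm markers, G2/M genes, NF-kB targets and the mitochondrial respiratory chain. They also differed after the low dose for Nrf2 targets, mismatch and nucleotide excision repair, labile regulators and translation factors, and between doses for Nrf2 targets, base excision repair, S-phase genes and translation factors.

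The log2 changes of the doses against the same controls were compared across the 8695 probe sets. They correlated at Pearson r = 0.42 and Spearman rho = 0.405, where 100 simulated sets of unchanged groups against the shared controls gave a mean r of 0.597 and at most 0.623. The covariance was 0.111 against 0.0368 in the simulations, a difference of 0.0746. The sign was the same for 63.9% of probe sets, and for 70.4% in the simulations. The simulated groups held no effect of either dose. Values of r and of the sign share below the simulated ones thus do not show that the doses acted in opposite ways. Higher in both were 237 probe sets, where independent lists would share 63.1, and lower in both 158 (58.9). Higher at the low and lower at the high dose were 58 (66.9), and the reverse held for 24 (55.5). The controls could not be split, since a part would hold fewer than 2 arrays, and part of the excess of shared calls may come from the shared controls. By gene, 150 were higher in both and 129 lower in both, while 48, with Gata6 and Foxq1 among them, were higher at the low and lower at the high dose, and 21, with Psat1 and Plac8 among them, the reverse.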

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

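The tests of a signal ceiling, of a ribosomal rise, of short-lived transcripts, of RNA quality, of the share of endoderm-like cells and of the scaling were chosen after the result was seen; the comparison of spreads and the other splits of the arrays were chosen before.

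The brightest probe sets were higher in both peroxide groups than in the controls, which separates the arrays along the line of treatment. A higher signal of ribosomal protein genes alone is argued against by the 3′ control probe sets of Gapdh and Actb. They read 3.11 and 2.36 times the controls at the low dose and 4.05 and 3.17 times at the high dose. The ribosomal median log2 change exceeded that of genes matched on treated signal by 0.09 at the low and -0.046 at the high dose. These were at the 71.2 and 40.1 percentile of 10000 random matched lists. This excess does not decide it, since matching on treated signal favours genes that rose. A ceiling on the signal of the control arrays may be a source and stays open. Outside the ribosomal and translation genes, 77.3% of the brightest probe sets were higher in both peroxide groups, between the bounds set. The spiked-in bacterial transcripts, which do not come from the cells, did not decide it. The log2 ratio of the brightest spike to a dimmer one differed by -0.11 (control minus treated, exact two-sided permutation p = 0.682, 220 splits), and the slope of one on the other, tested after that, by -0.77 (0.0531 on 3 control and 0.819 on 9 treated arrays, exact two-sided permutation p = 0.0545). Folds against the controls are therefore not established as changes in RNA for genes nearer the brightest control signal, such as Eef1a1 (4097 in the controls) and Apoe (5731). For values far below it a ceiling is not decided either. Of 42 tested probe sets above every control signal on all treated arrays, 5 read under 3603 on every control array. Rpl41 (157 in the controls) and a probe set of Rps28 (2159) were among these 5. The value of 3603 is 50% of the highest signal on the dimmest control array. Control probe sets were not counted. That of the B2 repeat met both conditions, at 1711 to 2251 on the control arrays and at least 12560 on each treated array. The count of 5 meets exactly a bound set after the values were seen. This count does not decide it. The deposited signals weigh each perfect-match probe against its mismatch partner and do not show saturation of single probes, which was not tested. An effect of peroxide on these transcripts was not tested apart from this and is open.

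Primitive endoderm markers were lower at the high dose by a median log2 change of -2.21. A general loss of short-lived transcripts is argued against, since labile chromatin and transcription regulators had a median of 0.040. Poorer RNA on the high-dose arrays is argued against as the whole cause. The mean Actb 3′/5′ ratio there was 0.974 times that of the controls (exact two-sided permutation p = 0.946), and the ratios of Gapdh, Tfrc and Pcx were 1.14, 0.826 and 0.638 times. Against the controls alone this does not decide, since the Actb value was 1.37 without control replicate 1. Those of Gapdh, Tfrc and Pcx were then 1.18, 0.910 and 1.24. Against the low-dose arrays the Actb value was 0.933 (0.883 to 0.975 without any single array), with 0.952 for Gapdh, 0.649 for Tfrc and 1.202 for Pcx. Between these doses the markers had a median of -2.48. The low-dose arrays, at 1.47 times the controls for Actb without control replicate 1, had a marker median of 0.28 against the controls. An effect of RNA quality on the markers that the low dose offset was not tested. A smaller share of endoderm-like cells at the high dose is a candidate explanation that these tests do not tell apart from lower expression within cells. No array holds cells from before the treatment, so a share that already differed then cannot be told apart either. Time limits lower expression within cells, since RNA was taken after 30 min of exposure and 1 h of recovery. Cells that began at the control level would have had to lose most marker RNA by then, 16.0-fold for Dab2. Labile regulators as a list showed no such loss. Half-lives of the marker RNAs were not measured, so how far the timing weighs against lower expression within cells is not decided. Of 12 markers with a control signal of 200 or more, 9 were at least 2-fold lower, or 75%, which meets exactly a bound set after the values were seen. Without Apoe (1.09), whose control signal a ceiling could bear on, it was 81.8% of 11. Apoe was also higher at the high than at the low dose, a difference in which the control arrays do not enter. A ceiling is thus no full ground for leaving it out. The share of endoderm-like cells was left open because Gata4 (-0.11) and Lamc1 (0.01) were not lower. Mean signal went from 1877 to 148 for Col4a1 and from 1634 to 317 for Lama1. For Sparc it went from 1146 ± 769 (SD, n = 3) to 175. Of the 19 markers 0 are on another list, and the data hold no cell counts.

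More probe sets differed from the controls at the low dose (2087) than at the high dose (1018). The scaling between arrays is argued against as the source, since under quantile and median scaling the count at the low dose was at least 2.23 times that at the high dose, against 2.05 with the deposited scaling. With array quality weights, which are no scaling, it was 1.53 times (2534 and 1655), the lowest of all settings tried. With the replicate number as a block it was 3.10 times (1852 and 597), the highest, and without control replicate 2 it was 2.91 times. The size of the gap thus depends on the setting. A larger spread among the high-dose arrays was not seen, with a median SD within the group 0.959 times that at the low dose (0.244 and 0.255). This does not decide the source. The groups shared 1 estimate of the spread, so a wider high-dose spread would raise the standard errors of both comparisons. Concentration and exposure time differ together, and a biological difference between the treatments stays open and untested.

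A chance division of these arrays is argued against as the source of the counts of changed probe sets. For the low dose against the controls, with 35 splits, a largest real split is the most this can show. Where arrays of a group share a culture, this does not cover a chance difference between cultures. Any difference in handling or scanning that runs along the groups is not covered either. The real split gave 1018 for the high dose against the controls, and the highest other of the 56 possible splits gave 1. For the low dose against the controls the real split gave 2087 and the highest other of 35 splits gave 613, and for the high against the low dose the real split gave 2385 and the highest other of 100 drawn splits gave 1087. In each of these comparisons 1 split, the real one, gave a count that large.

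Within groups of 4 or 5 arrays, a value far from the others by Dixon's criterion was found in 29 of 552 groups (254 genes and 22 array measures), or 5.25%, where chance gives about 1 in 20. High-dose replicate 2 stood apart in the signal of the middle 18S rRNA control probe set (56.5), the BioB spike (255), Actb (745), U2af2 (6792), Ccne1 (980), Tmsb4x (1098) and Uhmk1 (3525). Low-dose replicate 2 did so in Actb (1158), Eif3l (3472), Foxo3 (1726), Hmox1 (1270), Klf4 (3737) and Ccne1 (644). Low-dose replicate 1 did so in the 18S probe set (15.8), Lefty1 (233), Psmd8 (558), Cdc20 (3027) and Prdx3 (697), low-dose replicate 3 in Cenpa (310), Eif4g2 (507) and Rpa1 (1458), and low-dose replicate 4 in Pdia4 (297) and Rarg (103). High-dose replicate 1 did so in Foxq1 (21.1) and Nnt (290), high-dose replicate 3 in Uqcr11 (1610), high-dose replicate 4 in Col4a1 (197) and Prim2 (389), and high-dose replicate 5 in Cubn (66.8).

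The doses differed from each other, by limma's test of the difference itself, in 2385 probe sets. Median log2 differences, high minus low dose, were -0.46 for p53 targets, -0.49 for immediate-early genes, -2.48 for primitive endoderm markers, 0.24 for mitochondrial ribosomal proteins and 0.26 for the proteasome. Among genes that passed against the controls in opposite directions, log2 differences were -4.90 for Dab2, -4.31 for Gata6, -4.27 for Foxq1, -4.09 for Col4a1, -4.04 for Pdgfra, -3.44 for Amot, -2.28 for Gpx3, -1.62 for P4ha2, -1.60 for Cited2, -1.08 for Ercc5 and -1.07 for Eif4g2. The differences were 3.68 for Cdkn1c, 2.36 for Calml4, 2.31 for Plac8, 2.08 for Gap43, 1.99 for Sox11, 1.57 for Psat1 and 1.04 for Sod2.

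Some control probe sets, which entered no test of genes, were brighter on the treated arrays than on the control arrays, and others were not. The ratio of mean signals, treated over control, was 10.9 for the B2 repeat, 2.81, 2.56 and 2.40 for the 3′, 5′ and middle probe sets of Actb, and 3.63, 3.20 and 3.16 for those of Gapdh. The probe sets named for the opposite strand gave 2.85 and 3.39 for Actb and 5.78 and 3.4 for Gapdh. The B1 repeat read 2.05 times the control mean at the high dose and 0.831 times at the low dose, the 5′ 18S rRNA probe set 1.76 and 0.345 times, the BioC spike 0.977 and 1.33 times and the BioDn spike 0.947 and 1.16 times.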

How the results depend on the processing

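Leaving out probe sets of mean signal above 2000, and leaving out control replicate 1 and high-dose replicate 2 together, were chosen after the data were seen; the other alternatives were planned.

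Of 358 calls of named genes, 334 held under quantile normalization, 328 under median scaling, 354 with a floor and 357 with 4 times the offset. Of the 17 list calls, each held under median scaling, the floor, 4 times the offset, a mean over all probe sets of a gene, and fry, 15 under quantile normalization and 3 with an estimated correlation. Without probe sets of mean signal above 2000, 11 held, 5 were lost and 1 was reversed. Leaving out 1 array at a time kept 3991 of the calls of named genes and lost 305, and kept 202 list calls and lost 2 (the splicing factors at the high dose without control replicate 2 and the proteasome at the low dose without control replicate 1).

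The number of probe sets that differed between the high dose and the controls (1018) was 1655 with array quality weights, against 2534 for the low dose (2087), so that the low-dose count was 1.53 times the high-dose count instead of 2.05 times. With a minimum of 2-fold it was 280, against 536 for the low dose and 539 for high against low dose, by construction. Leaving out 1 array gave 490 to 1012 for the high dose, 1425 to 2141 for the low dose and 1994 to 2553 for high against low dose; without control replicate 2 it was 490 and without control replicate 3 it was 599. The cause was not tested.

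The number of lists past the threshold at the high dose (5) was 3 after quantile normalization, 3 without probe sets of mean signal above 2000, 8 without control replicate 1 and high-dose replicate 2 together, 2 with an estimated correlation and 10 by fry, and 4 to 8 with 1 array left out. At the low dose (7) it was 0 with an estimated correlation (6 at an unadjusted p under 0.05) and 15 by fry, and 7 to 9 with 1 array left out. For high against low dose (5) it was 1 with an estimated correlation and 15 by fry, and 5 to 6 with 1 array left out. Unlike camera, fry does not set a list against other genes. The correlation of the doses' log2 changes (0.42) was 0.388 after quantile normalization, 0.437 with a floor, 0.404 with the filter at the 50th percentile and 0.409 to 0.476 with 1 array left out. The cause was not tested.

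Without probe sets of mean signal above 2000 the median of the cytosolic ribosomal proteins at the high dose was reversed, to -0.051, as its brightest members were removed. Ldha at the high dose was reversed under quantile normalization, to -0.25.

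Of the other probe sets of genes called, 30 had the same call, 36 the same direction without passing and 28 the opposite direction. At the high dose the opposite values were 0.49 for Cox6b2, 0.34 for Cubn, 0.011 for Gata6, 0.021 for Lifr, 0.33 for Mki67, -0.26 for Mrpl50, -0.59 for Nanog, 0.52 for Pdgfra, -0.031 for Pkm, 1.01 for Pola2, -0.42 for Rpl19 and 0.97 for Slc2a3. At the low dose they were 0.43 for Bcl2l11, 0.27 for Eif1ax, 0.27 for Eif4e2, 0.98 for Fdps, 1.01 for Fth1, -0.0027 for Gata6, 0.053 and 0.40 for Hspa4, -0.40 for Pkm, 1.28 for Pola2 and 0.61 for Pold1. For high against low dose they were 0.55 for Cox6b2, -0.64 for Fdps, -0.28 and -0.70 for Hspa4, and -0.35 for Rpl19. Those that passed were Fth1, Pola2 at the low dose and the value of -0.70 for Hspa4, and why probe sets of a gene differed was not tested.

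Samples of different groups share replicate numbers, but the labels do not say that a number marks a pair. Deviations of 10 same-numbered pairs correlated at r = -0.178 to 0.148 and those of 37 other pairs at -0.162 to 0.177. Between low- and high-dose arrays, the same-numbered pairs 2 and 4 gave 0.148 and 0.113, and the highest other pair 0.111. Same-numbered pairs 1 and 3 gave -0.044 and 0.056. Whether the numbers pair the arrays is therefore open. With the replicate number as a block, 597 probe sets differed between the high dose and the controls, 313 of 358 calls of named genes and all 17 list calls held, and the correlation was 0.439. Of the 4 aminoacyl-tRNA synthetase genes higher at the high dose, 0 passed with the block in limma (5 of the 19 at an unadjusted p under 0.05).

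Signal over background limits the dim end: probe sets below the 30th percentile of mean log2 signal, with that of Jun among them, were not tested, and fold changes near the offset of 10.1 signal units are understated.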

Other observations

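The tests of individual aminoacyl-tRNA synthetase genes were made as part of all genes, but their choice as a group came after their values were seen, so these are values to look at again and not a test of the group.

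Cytosolic aminoacyl-tRNA synthetases charge tRNAs with amino acids, and 19 of their genes were measured. At the low dose 11 were lower than in the controls and 8 did not pass, with a median log2 change of -0.53. Lars had a log2 change of -1.08 ± 0.15 (SE), Sars of -0.99 ± 0.21, Mars1 of -0.86 ± 0.18 and Aars of -0.81 ± 0.13. The count was 7 without control replicate 1 and 12 under median scaling, where the median was -0.72. Between the doses 11 of the 19 were higher at the high dose, with a median of 0.64, and Sars (1.66), Aars (1.34) and Mars1 (1.33) differed the most. At the high dose 4 were higher than in the controls (Aars 0.53, Cars 0.51, Iars 0.43 and Sars 0.67), but this count was 0 in limma under median scaling, without control replicate 2 and without control replicate 3 (5, 4 and 6 at an unadjusted p under 0.05), 2 without any 1 of the high-dose arrays, 2 with no filter and 1 without a variance trend.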
